A study of Parachlorella kessleri with 6 samples.

How the data were processed

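Total RNA of Parachlorella kessleri was extracted with TRIzol, per the labels' protocols, from 3 control and 3 salt-stressed samples after 2 days. The labels name Illumina sequencing in the series design and a Proton library procedure in the extract protocol, and which one applies is not settled here. The aligner, the counting tool and their versions are not given in the sources used here.

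The deposited table holds whole-number read counts per assembled gene for each of the 6 libraries, per the file headers, with no normalization. It also holds FPKM values that the authors computed per library (fragments scaled by transcript length and library size), with 1 mean FPKM per group. The authors' log2 fold change was checked against the mean FPKM values: for 13091 genes it equals the log2 ratio after adding 0.1 to each mean, within 0.06, and for 9881 genes it is listed at 0. The deposited p-value and FDR columns come from a test whose name is not given in the sources used here. Every per-sample column was matched to a sample by its name. Identifiers begin with TRINITY, the prefix of the Trinity de novo assembler, and 58.9% of genes have no description; these hold 17.7% of all counts.

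Genes were tested on the counts with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter with a minimum count of 10, a quasi-likelihood fit on condition alone, and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the size of the fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries. At these depths 1 count is worth 0.0416 to 0.0608 CPM, and a count of 0 allows up to 3 counts per library, or 0.125 to 0.182 CPM; both cover counting error only. On simulated counts for 11438 genes of the salt against control comparison, with 200 genes changed, edgeR recovered 68.0% of genes changed 2-fold and 99.0% of those changed 4-fold, with 10 false calls, and DESeq2 recovered 76.0% and 99.0% with 32 false calls. The real comparison called 6616 genes and its replicate 1 libraries stand apart, which the simulation did not include. These rates therefore need not hold for it. A simulated list of 30 genes raised 1.5-fold was called by camera and 0 of the other lists were. The simulated genes were drawn independently, so this does not show how camera behaves where genes of a list are correlated. Estimated correlations in the real lists reached 0.454.

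Before the data were examined, 20 gene lists were fixed as word patterns applied to the gene descriptions, so that a list can hold genes whose name matches while their function differs. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 with an inter-gene correlation of 0.01, and p-values were adjusted over the 19 lists tested. Camera was repeated with the correlation estimated per list, and fry tested whether the genes of a list move one way on balance. The genes named were fixed by a rule: the 6 largest rises and 6 largest falls among called genes whose groups do not overlap, whose mean level is at or above the median and whose description names a function, 1 per description, and from each list the gene with the smallest p and the most abundant one. No pathway or ontology terms were used. Pfam domain families of 10 to 500 tested genes were compared with Fisher's exact test, an analysis added after the data were seen.

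Libraries with the same replicate number deviated from their group means together: the correlation of deviations across genes was 0.37, 0.16 and 0.22 for replicates 1, 2 and 3. The criterion used (every pair over 0.1) was met, but it cannot tell pairing by number from replicate 1 libraries that stand apart together. Deviations within a group cancel out, so a deviation shared by the replicate 1 libraries tends to make replicates 2 and 3 correlate. Salt replicate 3 deviated more with control replicate 2 (0.29) than with control replicate 3, and the labels do not say what the numbers mark. The fit with the replicate block is an alternative. Counts differed between every 2 replicates of a group by more than sampling noise, with a chi-square of 5.3 per gene for control replicates 2 and 3 and 34.4 or more for the others, so no library was counted as a duplicate.

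Other alternatives fixed before the data were seen were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, no filter, a filter of 10 counts in 3 libraries, a 2-fold minimum, leaving out each library, and 1 row per description in the lists. Added after the data were seen were library totals without TMM, a batch term for the replicate 1 libraries, replicates 2 and 3 alone, removal of rows matching amphibians, and removal of rows with an effective length under 300 bases. For the named genes the counts of all rows of a Trinity cluster, given by the identifier without its last part, were also summed, which was added after the data were seen. Effective length was computed from each gene's count, FPKM and library total. A pseudocount was not varied because the test runs on counts. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.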

Results

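RNA-seq was carried out on Parachlorella kessleri, a unicellular green alga related to Chlorella, grown for 2 days under control conditions or under salt stress. Each condition had 3 libraries, and the salt concentration was not given in the sources used here. The question was which transcripts differed between control and salt-stressed cells. The count table held 22972 assembled genes, each identified by a Trinity identifier and, for part of them, by the description of its best protein match in other organisms. Gene names used here are those of the best match and do not establish function in this alga. Library totals ranged from 16460455 counts in control replicate 3 to 24065705 in control replicate 1, and from 19849594 to 21654407 in salt. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

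The 6 libraries separated by condition. The first principal component of log2 CPM (counts divided by library size) held 83.0% of the variance and placed the control libraries between -81.6 and -77.2 and the salt libraries between 77.9 and 81.2. The second component held 10.4% and set control replicate 1 (52.7) and salt replicate 1 (19.6) apart from the other 4 libraries, which lay between -29.0 and -7.3. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.992 between control replicates 2 and 3, 0.961 and 0.965 between control replicate 1 and these, and 0.980 to 0.988 among the salt libraries. Between conditions it was 0.822 to 0.841. Sequences of other origin divided the libraries in the same way. TRINITY_DN2345_c0_g1, a row with phage replication and capsid domains, held 12699 counts in control replicate 1 and 21047 in salt replicate 1 and 0 in each of the other 4 libraries, which allows up to 0.182 CPM there. Rows whose best match was an amphibian protein summed to 3865 counts in control replicate 2, 199 in control replicate 3, 279 and 550 in salt replicates 2 and 3, and 20 and 4 in control and salt replicate 1. Rows matching cotton (5038, 4874 and 3740 counts in the control libraries, 4239, 4461 and 3956 in the salt libraries) did not follow this division. Nor did rows matching Staphylococcus, with 418, 312 and 167 counts in control and 991, 1197 and 1086 in salt. These were higher in every salt library than in any control library, and so divided by condition. The labels name no batch, and the calls below come from a fit without a batch term.

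**Figure D1:**
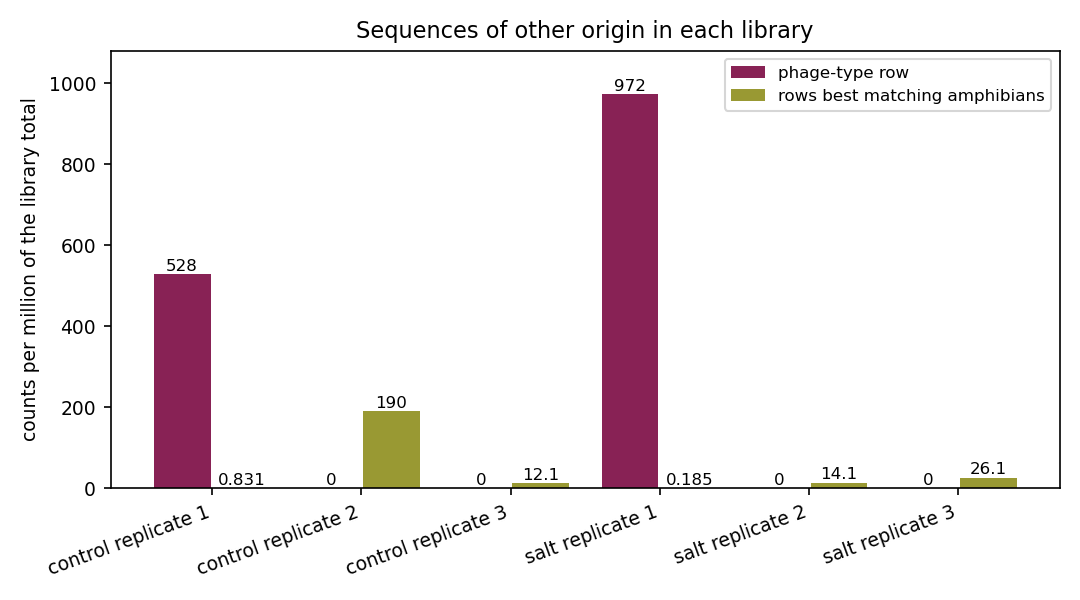
CPM by library total (vertical axis, linear) in each of the 6 libraries for the phage-type row TRINITY_DN2345_c0_g1 and for the sum of rows whose best match is an amphibian protein. The phage-type row reaches 528 CPM in control replicate 1 and 972 in salt replicate 1, and the amphibian sum is highest in control replicate 2, at 190.

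In salt, most genes of chlorophyll synthesis and many of light harvesting, of plastid and mitochondrial ribosomes and of DNA replication were higher, while many lipid breakdown genes and signalling kinases were lower. As lists, 5 of these 6 groups were no longer called when the correlation between genes was estimated: adjusted p = 0.0843, 0.494, 0.173 and 0.499 with an estimated correlation for the raised lists in that order, and 0.0843 for lipid breakdown. Signalling kinases were still called (0.000129). Their estimated correlation (-0.001) lay below the preset value, so for them the estimate was the more lenient setting and no further check. Glutamate-1-semialdehyde aminomutase (TRINITY_DN5113_c0_g2), which makes the tetrapyrrole precursor aminolevulinate, went from 32.5 ± 0.602 CPM in control to 442 ± 22.2 CPM in salt (mean ± SD, n = 3 each). Malate synthase (TRINITY_DN5425_c2_g1), an enzyme of the glyoxylate cycle, went from 1051 ± 79.0 to 238 ± 13.5 CPM. Of 11438 genes tested with edgeR's quasi-likelihood test, 6616 (57.8%) changed at a Benjamini-Hochberg adjusted p under 0.05, 3331 raised and 3285 lowered in salt. At a change of at least 2-fold, 1814 were raised and 2020 lowered. With library totals alone as the scaling, 4064 genes were raised and 2658 lowered (60.5% raised, against 50.3%), since the median log2 fold change then moved by 0.19. Fold changes below are relative to the TMM scaling.

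Among the abundant genes with a functional description, the 6 largest rises were in genes of varied function. A cobalamin-independent methionine synthase (TRINITY_DN5638_c2_g5) had the largest, from 2.07 ± 1.41 to 280.5 ± 84.9 CPM (n = 3 each; log2 fold change 7.09, SE 0.61, edgeR adjusted p = 0.000139). A pherophorin-type protein named chitin-binding lectin 1 (TRINITY_DN4641_c0_g7) rose by a log2 fold change of 6.30 (SE 0.32, adjusted p = 2.47e-05). A gene named viral protein TPX (TRINITY_DN4630_c2_g4), which carries Barwin and LysM domains, rose by 5.93 (SE 0.78, adjusted p = 0.00072), and a MatE-type multidrug transporter (TRINITY_DN4382_c5_g3) by 5.28 (SE 0.35, adjusted p = 5.74e-05). A delta-12 fatty acid desaturase (TRINITY_DN4714_c0_g1), of the enzymes that make linoleic acid, rose from 10.8 ± 4.70 to 309 ± 24.1 CPM (log2 fold change 4.84, SE 0.37, adjusted p = 8.96e-05). A cyclic nucleotide-gated cation channel (TRINITY_DN4844_c1_g8) rose from 4.06 ± 0.973 to 115 ± 7.59 CPM (4.83, SE 0.21, adjusted p = 1.9e-05). The 6 largest falls were also in genes of varied function. A subtilisin-type serine proteinase (TRINITY_DN5182_c0_g1) went from 987 ± 174 to 3.08 ± 1.58 CPM (log2 fold change -8.32, SE 0.48, adjusted p = 3.48e-05), and the related protease Epr (TRINITY_DN4713_c2_g3) changed by -7.98 (SE 0.54). Aldehyde dehydrogenase 2B4 (TRINITY_DN5986_c9_g7) changed by -7.42 (SE 0.54), an alcohol dehydrogenase (TRINITY_DN5943_c5_g4) by -7.00 (SE 0.47) and a RasGEF domain kinase (TRINITY_DN4841_c1_g7) by -6.58 (SE 0.21), each with an edgeR adjusted p of at most 7.61e-05. An ABC transporter named canalicular organic anion transporter 1 (TRINITY_DN5377_c3_g2) changed by -5.88 (SE 1.16, adjusted p = 0.00449). Its control values were 374 CPM in replicate 1 and 4547 and 4484 CPM in replicates 2 and 3, against 13.7 to 92.3 CPM in salt.

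These 12 genes share a Trinity cluster with other rows, and the change of the summed cluster, computed after these values were seen and scaled by library total, was smaller. For the 6 rises the summed log2 fold change was 0.81 for the methionine synthase cluster, 1.21 for the lectin, 1.70 for TPX, 0.49 for the transporter, 1.64 for the desaturase and 0.52 for the cation channel. Those of the methionine synthase, transporter and cation channel thus stayed within 2-fold, and whether reads passed between rows of these clusters is not settled. For the falls it was -4.27 for the subtilisin-type proteinase, -1.13 for Epr, -3.50 for aldehyde dehydrogenase, -2.86 for alcohol dehydrogenase, -1.08 for the RasGEF kinase and -4.86 for the ABC transporter. Among genes named below, summed clusters also stayed within 2-fold for fructose-1,6-bisphosphatase (0.58), the ammonium transporter (0.52), ubiquitin-60S ribosomal protein L40 (0.54), glycerol-3-phosphate acyltransferase (0.99), sucrose synthase (-0.82), NADH glutamate synthase (-0.51) and the threonyl-tRNA synthetase (-0.82). The catalase cluster changed by 0.99, opposite in sign to the gene itself. The clusters of glutamate-1-semialdehyde aminomutase (3.28) and malate synthase (-2.05) moved with the gene.

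Chlorophyll and heme synthesis genes were higher in salt. Of 31 genes tested in this list, 25 rose, 5 fell and 1 was not called, with a median log2 fold change of 1.88 (1.5 within the replicate 1 pair and 1.64 within replicates 2 and 3). Counts adjusted over the list alone were also 25 and 5. The magnesium chelatase subunits that insert magnesium into protoporphyrin had members that rose, with log2 fold changes of 3.62 (SE 0.22) for ChlH (TRINITY_DN5006_c0_g1), 2.85 (SE 0.21) for ChlI (TRINITY_DN5729_c1_g3) and 1.88 (SE 0.14) for ChlD (TRINITY_DN4693_c0_g1). Chlorophyll synthase (TRINITY_DN5558_c3_g5) rose by 3.36 (SE 0.39), and the most abundant member, coproporphyrinogen oxidase (TRINITY_DN5925_c0_g1), went from 326 ± 46.3 to 955 ± 280 CPM (log2 fold change 1.55, SE 0.25, edgeR adjusted p = 0.00174). Not every copy rose. A second gene named magnesium chelatase subunit H (TRINITY_DN5079_c0_g1) fell (-0.64, SE 0.14, adjusted p = 0.00776), as did a porphobilinogen deaminase (TRINITY_DN5868_c1_g3; -2.70, SE 0.29) and ferrochelatase (TRINITY_DN5896_c2_g2), which makes heme (-0.65, SE 0.13, adjusted p = 0.00487). These members outside the rule for named genes were chosen after their values were seen. The camera test gave an adjusted p of 2.3e-05 over 19 lists, and adjusted p = 0.0843 with an estimated correlation.

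**Figure D2:**
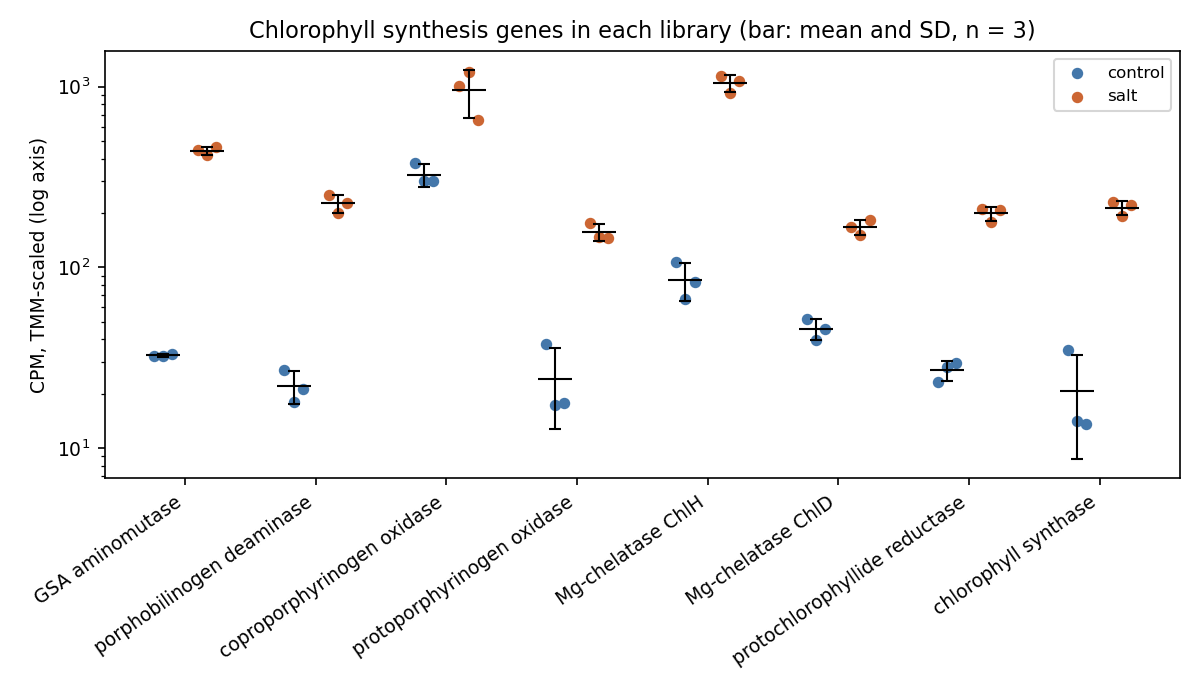
TMM-scaled CPM (vertical log axis) of 8 chlorophyll synthesis genes in each of 3 control and 3 salt libraries; points are libraries, bars are the mean and SD. For each of the 8 genes the 3 salt libraries lie above the 3 control libraries, as for ChlH, with means of 85.2 and 1050 CPM; the 8 were chosen after their values were seen, and 5 other genes of the list fell.

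Of 60 photosystem and light-harvesting genes, 36 rose, 0 fell and 24 were not called, as also when adjusted over the list alone. The median log2 fold change was 1.02, with 1.70 within the replicate 1 pair and 0.73 within replicates 2 and 3. Oxygen-evolving enhancer protein 1 (TRINITY_DN3879_c1_g1) of the water-splitting complex rose from 32 ± 3.56 to 113 ± 22.3 CPM (log2 fold change 1.82, SE 0.17, edgeR adjusted p = 0.000196). The most abundant member, a chlorophyll a-b binding protein (TRINITY_DN5466_c1_g1), went from 1313 ± 442 to 2775 ± 995 CPM (1.08, SE 0.35, adjusted p = 0.0331). That call was lost with the replicate block (adjusted p = 0.0648), without control replicate 3 (0.0554) and without salt replicate 1 (log2 fold change 0.74, adjusted p = 0.107). Core subunits that plastid genomes of green algae encode were not called, with values of -0.04 for PsaA (TRINITY_DN5433_c2_g1), -0.63 for CP43 (TRINITY_DN2508_c0_g1) and 0.44 for CP47 (TRINITY_DN689_c0_g1); they were chosen after their values were seen and lay below 10 CPM. The list's camera adjusted p was 2.3e-05, and adjusted p = 0.494 with an estimated correlation. Of the 60 rows, 40 had an effective length under 300 bases. Of the other 20, 5 were raised, against 3096 of all 10080 tested genes of that length; with these alone the list's adjusted p was 0.249 and its median 0.67.

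Plastid and mitochondrial ribosomal protein genes had 17 raised, 4 lowered and 11 not called of 32 (18 and 4 adjusted over the list alone), with a median log2 fold change of 0.83, or 0.94 and 0.71 within the replicate 1 pair and within replicates 2 and 3. Ribosomal protein S1 (TRINITY_DN659_c0_g1) rose by 2.49 (SE 0.15, edgeR adjusted p = 4.47e-05), whereas the most abundant member, L6 (TRINITY_DN4407_c0_g1), changed by -1.52 (SE 0.16, adjusted p = 0.000297). The camera adjusted p was 0.00632, and adjusted p = 0.173 with an estimated correlation. In contrast, 90 of 105 cytosolic ribosomal protein genes were not called, 12 rose and 3 fell (5 and 0 adjusted over the list alone; median 0.18, camera adjusted p = 0.166). Of these 105, 84 had an effective length under 300 bases. The list passed without control replicate 1 (adjusted p = 0.0397) and without salt replicate 2 (0.0236). Its median turned to -0.09 without salt replicate 1 (camera adjusted p = 0.978) and to -0.14 with no filter on low counts (0.821). Ubiquitin-60S ribosomal protein L40 (TRINITY_DN4422_c0_g7) rose by 3.57 (SE 0.24, adjusted p = 5.97e-05) at a low level, and L35a-2 (TRINITY_DN5904_c2_g1) had 1397 ± 113 CPM in control and 1353 ± 181 CPM in salt (-0.05, SE 0.16).

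Of 58 DNA replication and cell cycle genes, 27 rose, 7 fell and 24 were not called, with equal counts adjusted over the list alone. The median log2 fold change was 0.55, with 0.55 within the replicate 1 pair and 0.61 within replicates 2 and 3. The helicase subunits MCM7 (TRINITY_DN5579_c2_g1) and MCM2 (TRINITY_DN5045_c4_g3) rose by 1.99 (SE 0.17) and 1.73 (SE 0.16), and the catalytic subunit of DNA polymerase epsilon (TRINITY_DN4277_c0_g1) by 1.90 (SE 0.22); these were chosen after their values were seen. A CDC2-type kinase (TRINITY_DN5010_c1_g1) had the smallest p and fell, with a log2 fold change of -1.77 (SE 0.12, edgeR adjusted p = 5.74e-05). A septin (TRINITY_DN4210_c0_g1) had -0.02 (SE 0.54), and without control replicate 1, where it reached 1550 CPM against 382 and 394 in the other controls, 0.98 (adjusted p = 0.00111). The camera adjusted p was 0.0192, and adjusted p = 0.499 with an estimated correlation. With rows of 300 bases or more it was 0.0513, while the median was 0.57.

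Lipid breakdown and beta-oxidation genes were lowered more often than raised in salt, with 19 of 40 lowered, 4 raised and 17 not called, and equal counts adjusted over the list alone. The median log2 fold change was -0.57, with -0.61 and -0.37 within the replicate 1 pair and replicates 2 and 3. Malate synthase (TRINITY_DN5425_c2_g1) changed by -2.14 (SE 0.13, edgeR adjusted p = 4.47e-05) and isocitrate lyase (TRINITY_DN5461_c4_g2), the other enzyme specific to the glyoxylate cycle, by -1.85 (SE 0.24). The triacylglycerol lipase SDP1 (TRINITY_DN5093_c1_g2) changed by -1.53 (SE 0.13), and peroxisomal 3-ketoacyl-CoA thiolase 2 (TRINITY_DN4707_c5_g3) by -2.83 (SE 0.64, adjusted p = 0.00821). Of the 4 raised members, 2-isopropylmalate synthase (TRINITY_DN5986_c8_g1), an enzyme of leucine synthesis, and PASTICCINO 2 (TRINITY_DN5401_c2_g1), an enzyme of fatty acid elongation, do not break down lipids. Another, acyl-protein thioesterase 1 (TRINITY_DN5860_c1_g2), is named for its action on proteins. Of the 19 lowered genes, 6 carry the malate synthase name and have identifiers that begin with TRINITY_DN5425. The camera adjusted p was 0.0192. It was adjusted p = 0.0843 with an estimated correlation, 0.0729 with 1 row per description and 0.129 with rows of 300 bases or more, of which 13 of 33 were lowered. With those rows alone the median was -0.25, and the 7 shorter rows had a median of -1.85 in the main fit.

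Signalling kinases and calcium sensors had 25 of 40 genes lowered, 4 raised and 11 not called (26 and 4 adjusted over the list alone), with a median log2 fold change of -0.53, or -0.68 within the replicate 1 pair and -0.54 within replicates 2 and 3. The energy-sensing SNF1-related kinase KIN11 (TRINITY_DN4223_c0_g1) went from 194 ± 14.6 to 71.4 ± 4.54 CPM (log2 fold change -1.44, SE 0.11, edgeR adjusted p = 9.5e-05). Mitogen-activated protein kinase 4 (TRINITY_DN5443_c2_g1) changed by -1.33 (SE 0.13), and mitogen-activated protein kinase homolog 1 (TRINITY_DN3213_c0_g1) rose by 2.09 (SE 0.25). The most abundant member (TRINITY_DN5744_c0_g5), a kinase of the same cascade, had 0.08 (SE 0.22), and without control replicate 1 it had 0.34 (adjusted p = 0.038). The list's camera adjusted p was 0.00113, and adjusted p = 0.000129 with an estimated correlation. It was the only list called with both correlations. Its estimated correlation was -0.001, below the preset value, which makes the p-value smaller. For this list the estimated correlation was thus the more lenient setting, and the repeated call is no further check.

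**Figure D3:**
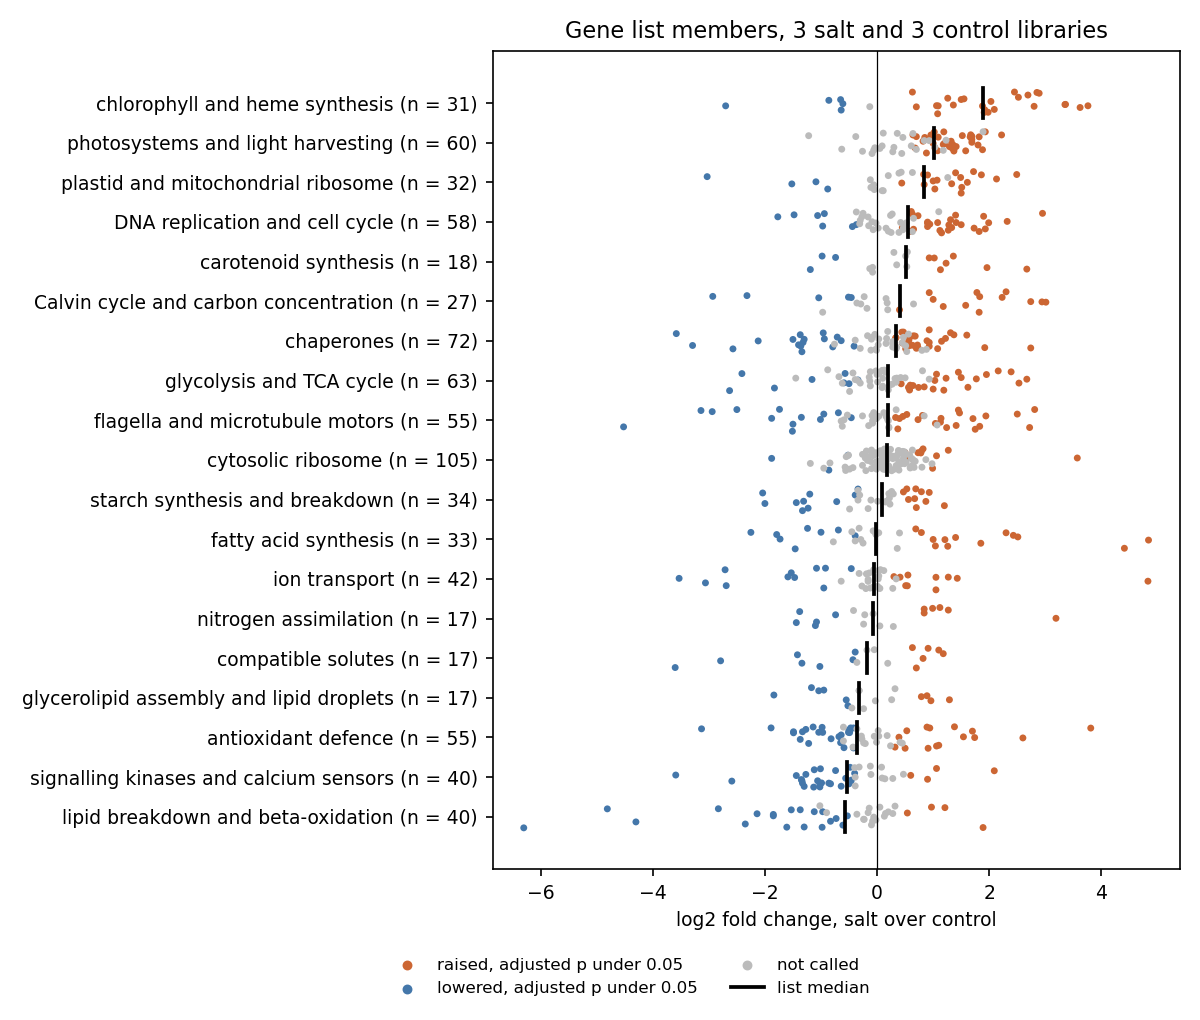
Log2 fold change in salt over control (horizontal axis) of each tested member of 19 gene lists; orange points were raised and blue points lowered at an edgeR adjusted p under 0.05, grey points were not called, and black bars are list medians. Medians run from -0.57 for lipid breakdown to 1.88 for chlorophyll and heme synthesis.

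The other 12 tested lists were not called by camera. Carbon fixation genes had 13 raised and 5 lowered of 27 (median 0.40, 1.33 within the replicate 1 pair and 0.22 within replicates 2 and 3; adjusted p = 0.106, and 0.0463 without control replicate 3). Plastid fructose-1,6-bisphosphatase (TRINITY_DN4535_c0_g8) of the Calvin cycle rose by 2.30 (SE 0.11, edgeR adjusted p = 2.4e-05). The most abundant member, the Rubisco small subunit (TRINITY_DN5968_c2_g4), had -0.46 (SE 0.14, adjusted p = 0.0289), lost without control replicate 2 (0.0802), control replicate 3 (0.107), salt replicate 2 (0.0991) or salt replicate 3 (0.0813), and with upper-quartile factors (0.0627) or library totals (0.124). Glycolysis and TCA cycle genes had 21 raised and 8 lowered of 63 (median 0.20, adjusted p = 0.106, 0.0475 with no filter on low counts). Pyruvate dehydrogenase E1 beta of the plastid (TRINITY_DN4052_c0_g2), which makes acetyl-CoA, rose by 2.67 (SE 0.12), and a pyruvate:ferredoxin oxidoreductase-type gene (TRINITY_DN5899_c0_g1) had -0.88 (SE 0.56). Carotenoid genes had 7 raised and 3 lowered of 18 (median 0.52, adjusted p = 0.186). Zeta-carotene desaturase (TRINITY_DN5520_c6_g1) rose by 1.96 (SE 0.13), and zeaxanthin epoxidase (TRINITY_DN4838_c1_g3) had -0.74 (SE 0.23, adjusted p = 0.0265), lost without salt replicate 1 (0.0685) or salt replicate 3 (0.0947). Starch genes had 10 raised and 10 lowered of 34 (11 and 10 adjusted over the list alone; median 0.08, mean -0.14, camera direction down, adjusted p = 0.916). Beta-amylase 3 (TRINITY_DN5887_c3_g2), a starch-degrading enzyme, went from 1068 ± 105 to 267 ± 11.8 CPM, and cytosolic glucan phosphorylase (TRINITY_DN5388_c0_g2) had 0.01 (SE 0.14).

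Fatty acid synthesis genes had 13 raised and 8 lowered of 33 (median -0.02, mean 0.41, camera direction up, adjusted p = 0.498). A 3-oxoacyl-ACP enzyme (TRINITY_DN3752_c0_g1) rose by 2.43 (SE 0.15), and an omega-6 desaturase (TRINITY_DN4714_c0_g5) by 2.30 (SE 0.19). That row lies in the same Trinity cluster as the delta-12 desaturase above, so their separate values are uncertain. Glycerolipid assembly had 4 raised and 6 lowered of 17 (5 and 6 adjusted over the list alone), with a median of -0.32 and a camera adjusted p of 0.596. With an estimated correlation, which was negative (-0.059) and so makes the p-value smaller, the camera adjusted p was 0.0129. Plastid glycerol-3-phosphate acyltransferase (TRINITY_DN4427_c0_g2) rose by 1.29 (SE 0.10), and the delta-7 desaturase (TRINITY_DN5316_c2_g1) had -0.45 (SE 0.17, adjusted p = 0.0594, and 0.0457 with the replicate block). Genes for compatible solutes had 6 raised and 7 lowered of 17 (6 and 8 adjusted over the list alone; median -0.18, adjusted p = 0.596). Diacylglycerol kinase (TRINITY_DN5227_c1_g2), which is not an enzyme of solute synthesis, had -3.60 (SE 0.14), and sucrose synthase (TRINITY_DN5923_c0_g2) -1.02 (SE 0.13), both past the threshold. Ion transport had 10 raised and 11 lowered of 42 (median -0.06, adjusted p = 0.666). The cation channel TRINITY_DN4844_c1_g8 above had its smallest p, and the vacuolar proton-pumping pyrophosphatase (TRINITY_DN5757_c10_g4) rose from 568 ± 55.6 to 1529 ± 154 CPM. Nitrogen assimilation had 6 raised and 5 lowered of 17 (6 and 6 adjusted over the list alone; median -0.07, mean 0.11, camera direction down, adjusted p = 0.873). An ammonium transporter (TRINITY_DN5043_c0_g3) rose by 3.19 (SE 0.30), and NADH glutamate synthase (TRINITY_DN5946_c0_g2) fell (-1.10, SE 0.16). With library totals as the scaling, the medians of the solute, fatty acid, ion transport and nitrogen lists were above 0.

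Antioxidant genes had 15 raised and 24 lowered of 55 (15 and 26 adjusted over the list alone; median -0.36, camera adjusted p = 0.26). The smallest p belonged to a gene whose matches name both threonyl-tRNA synthetase and alternative oxidase (TRINITY_DN4939_c0_g1; -1.33, SE 0.10), and catalase (TRINITY_DN5788_c1_g4) had -0.60 (SE 0.27, edgeR adjusted p = 0.0953, and 0.0484 with DESeq2). Chaperones had 28 raised and 17 lowered of 72 (median 0.33, adjusted p = 0.23, and 0.0477 within replicates 2 and 3). A DnaJ protein (TRINITY_DN5581_c1_g4) had -2.12 (SE 0.18, adjusted p = 0.000135), and mitochondrial chaperonin 60 (TRINITY_DN5666_c1_g1) 0.63 (SE 0.17, adjusted p = 0.0153), lost without control replicate 2 (0.0626) or control replicate 3 (0.0679). Flagella and microtubule motor genes had 21 raised and 13 lowered of 55 (21 and 14 adjusted over the list alone; median 0.19, adjusted p = 0.618). A flagellar associated membrane protein (TRINITY_DN5942_c2_g1) changed by -4.52 (SE 0.18). A kinesin-like calmodulin-binding protein (TRINITY_DN5304_c0_g1) had -0.46 (SE 0.16, adjusted p = 0.0419), lost without control replicate 2 (0.0787), control replicate 3 (0.059), salt replicate 1 (0.0703), salt replicate 2 (0.129) or salt replicate 3 (0.0811), and with upper-quartile factors (0.0607), library totals (0.118) or no filter (0.0864). Where no second pair of counts is given for one of the 19 tested lists, the counts adjusted over the list alone were equal. The list of bacterial sequence held 1 tested gene, an IS1 transposase (TRINITY_DN5317_c1_g1), with 12.8 CPM in control replicate 1 and 0.461 to 1.14 CPM in the other libraries (-2.67, SE 1.08, adjusted p = 0.071; 0 raised and 1 lowered when adjusted over the list alone). Its adjusted p was 0.0348 without control replicate 2, 0.0401 without control replicate 3 and 0.0378 with the batch term (log2 fold change -1.91). Without control replicate 1 its log2 fold change was -0.36 (adjusted p = 0.513), and within replicates 2 and 3 it was -0.72 (adjusted p = 0.155).

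The authors' deposited table marks 4300 genes as significant, 2069 raised and 2231 lowered in salt. All 4300 have an absolute log2 fold change of at least 1, a minimum that the 6616 calls here do not have. Of these, 3866 were among the genes tested here, 3776 were called by the edgeR fit, all 3776 in the direction that the authors' deposited table gives, and 90 were not called. Of the 3834 genes called here with at least a 2-fold change, 3659 were marked in the authors' deposited table. The median difference between the log2 fold change of the authors' deposited table and that of the edgeR fit was 0.04.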

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

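The tests of the batch, of salt as the origin of these sequences, of summed clusters and of other splits were chosen after the results were seen; those of length and abundance, partner rows within clusters, shared best matches and best-match organism were set before their results. A signal appeared in data outside the comparison: TRINITY_DN2345_c0_g1, with phage replication and capsid domains, was not tested because 4 libraries hold 0 counts of it, yet it had 21047 counts in salt replicate 1 against 12699, 0 and 0 in the control libraries.

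That row is 1 of 54 rows with over 95% of their CPM in control replicate 1 and salt replicate 1, while the highest number for any other pair of a control and a salt library was 10. None of the 54 was tested for salt. These rows were picked by their counts in the replicate 1 libraries, so the 16681 in control replicate 1 cannot test a response to salt. For the phage-type row, 12699 counts in control replicate 1 and 0 in salt replicates 2 and 3 argue against such a response. A separate library or sequencing batch for the replicate 1 libraries is consistent with the number of 54, and also with 63 rows found in all 4 libraries of replicates 2 and 3 and in neither replicate 1 library, against at most 2 for other sets of 2 control and 2 salt libraries. Not every sequence of other origin divides this way: rows matching cotton held 5038 and 4239 counts in the replicate 1 libraries and 3740 to 4874 in the others. Rows matching Staphylococcus divided by condition instead, with 167 to 418 counts in the control libraries and 991 to 1197 in the salt libraries. Where the sequences came from was not tested, although phages of this type serve as sequencing controls.

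In salt, 36 of 60 photosystem genes and 25 of 31 chlorophyll synthesis genes rose. As lists, neither was called with the correlation estimated (adjusted p = 0.494 and 0.0843 with an estimated correlation). Of the 36 raised photosystem genes, 5 were among the 20 with an effective length of 300 bases or more. The replicate 1 libraries hold a control and a salt library, so a shift shared by both largely cancels between the conditions. The within-batch medians were thus a weak test of the batch as the whole cause, and their bound of 0.5 was set with the values in view. The smaller was 0.73 (the other 1.70) for photosystem genes and 1.5 (the other 1.64) for chlorophyll genes. Both lists were thus higher in salt on either side of the division. The medians after removing a trend with effective length and abundance, fitted on other genes, were 1.79 (bootstrap SE 0.26) and 1.93 (SE 0.24). They argue against that trend as the whole cause, but it held only 3.7% and 3.3% of the variance of fold changes. Its removal raised the medians, from 1.02 and 1.88. The SEs resample genes, not libraries. For photosystem genes the call was nevertheless lost when rows under 300 bases were left out (adjusted p = 0.249, median 0.67), which left 20 of 60 rows. A response to salt, and a difference in culture density or stage on day 2, may both underlie these changes and stay open, untested.

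Of the tested genes, 111 changed by over 32-fold with over 20 CPM in the higher condition, 42 higher in salt and 69 higher in control. The lower condition held under 1 CPM for 63 of them and up to 53.4 CPM for the others. Reads exchanged between rows of 1 Trinity cluster stay open for the set. In 84 of the 111 the cluster held other rows with over 1 CPM, and of these 84 the summed cluster still changed by over 32-fold in 23.8% (95% Wilson interval 16 to 33.9) and stayed within 2-fold in 32.1%. Where it stayed within 2-fold, in 33.3% (18.6 to 52.2) the rest of the cluster moved the opposite way by a like amount. The cysteine proteases TRINITY_DN5154_c0_g5 (76.3 CPM in control, 0.134 in salt) and TRINITY_DN5154_c0_g6 (0 counts in control, 24.1 CPM in salt) lie in 1 such cluster and moved opposite ways by unlike amounts; they were chosen after their values were seen. Sequence variants splitting 1 gene over opposite rows cannot be excluded: of 50 rows with a best match, 14% (7.0 to 26.2) had an opposite row with that match, against 10.9% of other rows changed over 4-fold. An organism present in 1 condition alone also stays open, since 76.0% (62.6 to 85.7) matched a green alga or land plant, against 86.4% of other rows, and 61 rows had no match. The intervals given here treat rows as independent, but rows of 1 cluster share its summed change and can share a best match. These intervals are therefore likely too narrow.

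Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 6616 genes and was the only 1 of the 10 with any call, the highest other count being 0 in the edgeR fit, where up to 320 genes had an unadjusted p under 0.05. For gene lists the real split called 6, and 4 of the 10 splits, the real one included, called as many or more, the highest other count being 9. Among the 4 splits that part every replicate pair, the others called 7, 7 and 1 lists. Every other split mixes control and salt libraries on each side, which widens the spread within a side and keeps part of the salt difference. The lack of called genes there can follow from the mixing alone, and lists called there need not be false calls. The splits therefore decide neither question. The list p-values of camera with a preset correlation are read here beside those with an estimated correlation.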

How the results depend on the processing

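Library totals, the batch term, replicates 2 and 3 alone, removal of amphibian rows and of short rows were chosen after seeing the data. The count of 6616 changed genes lay between 5515 and 7372 when each library was left out (raised 2750 to 3785, lowered 2711 to 3587), was 6943 with the DESeq2 Wald test, 6846 with the replicate block, 7542 with the batch term and 7874 within replicates 2 and 3, and moved by over 1.5 times only with the 2-fold minimum, to 3834 (1814 raised, 2020 lowered). With the replicate block 6390 of the 6616 calls were kept; among the named genes 2 changed side and the lists called stayed 4 raised and 2 lowered. Of the changed genes, 82.6% to 96.7% were called again with 1 library left out, all in the same direction.

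The 4 lists raised became 0 with an estimated correlation, 8 with fry and 2 with rows of 300 bases or more, and the 2 lists lowered became 5 with fry, 1 with 1 row per description and 1 with rows of 300 bases or more; with a library left out they were 4 to 5 and 2. Fry does not compare a list with other genes. The length filter leaves fewer genes, but DNA replication lost its call with 57 of 58 rows kept. The lipid breakdown median moved from -0.57 to -0.25 under that filter, and that of photosystems from 1.02 to 0.67. No cause was tested for that filter or for the other settings. Over 19 alternatives camera or fry adjusted p ran from 1.93e-09 to 0.0843 for chlorophyll synthesis, 2.33e-06 to 0.494 for photosystems, 0.00055 to 0.173 for plastid ribosome, 0.00055 to 0.499 for DNA replication, 0.00115 to 0.129 for lipid breakdown and 0.000107 to 0.00197 for signalling kinases.

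Of 50 named genes, 42 were called and 37 of these kept their side of the threshold in every alternative. TRINITY_DN4210_c0_g1 turned from -0.02 (not called) to 0.93 within replicates 2 and 3 and to 0.98 without control replicate 1 (range -0.34 to 0.98 with a library left out); the cause was not tested. Genes at few counts are limited by depth, since 1 count is 0.0416 to 0.0608 CPM.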

Other observations

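The domain analysis and the genes named from it were chosen after seeing the data. Protein kinase genes, from which members of the fixed list were not removed, fell more often in salt than genes with a domain in general. Of 230 tested genes with a Pkinase domain, 116 fell and 43 rose (50.4% lowered, against 26.1% of all genes with a domain). Fisher's exact test, one-sided, gave adjusted p = 3.56e-13 over 450 tests. With library totals 95 fell and 50 rose. Protein phosphatases of the PP2C type, which oppose kinases, had 15 of 24 lowered and 4 raised (adjusted p = 0.0119), against 13 and 5 with upper-quartile factors and 11 and 6 with library totals. Genes with the SBP domain, a DNA-binding domain of plant and algal transcription factors, had 12 of 16 lowered and 0 raised (adjusted p = 0.00667); with upper-quartile factors or library totals 10 were lowered and 2 raised. The most abundant of the SBP genes with the smallest p values (TRINITY_DN5877_c0_g1) went from 1633 to 297 CPM, a log2 fold change of -2.46 (edgeR adjusted p = 4.24e-05). Genes with a PAS_8 domain, of a sensor type, had 11 of 17 lowered and 2 raised (adjusted p = 0.0414), among them a phototropin (TRINITY_DN5432_c1_g1), a blue-light receptor, with -2.77. The test treats genes as independent and rows of 1 gene can be counted more than once.

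Genes with an AMP-binding domain, found in acyl-CoA synthetases and peptide synthetases, had 16 of 25 lowered and 1 raised (adjusted p = 0.00667), and those with a PP-binding domain 9 of 11 lowered and 1 raised (adjusted p = 0.0119). Armadillo repeat genes had 17 of 24 lowered and 2 raised (adjusted p = 0.000843), with an importin alpha (TRINITY_DN6010_c4_g2), a nuclear import receptor, at -2.06. Only 2 families were enriched among raised genes. Genes with the GTP-binding domain of elongation factors had 15 of 21 raised and 1 lowered (adjusted p = 0.0264), with plastid elongation factor G (TRINITY_DN5550_c0_g15) at 2.24 and initiation factor IF-2 (TRINITY_DN2448_c0_g1) at 2.21. Methyltransferase genes of the Methyltransf_31 family had 20 of 30 raised and 3 lowered (adjusted p = 0.0151), with a sterol C-methyltransferase (TRINITY_DN5503_c0_g2) at 2.20. With library totals the lowered and raised counts were 14 and 1 for AMP-binding, 7 and 1 for PP-binding, 15 and 2 for armadillo repeat and 10 and 2 for PAS_8 genes. The medians of these families kept their sign under the other scalings.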
